A study of Mus musculus with 2 samples.

How the data were processed

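Single-cell libraries of mouse hepatocytes in 3D culture were made with a droplet protocol (10x Genomics Chromium), per the labels' protocols. The deposited files hold UMI counts per gene and cell barcode, not normalized, for 1 library in expansion medium and 1 in induction medium. The counts were made with Cell Ranger 2.1.1 and genome build mm10, per the submitters' processing notes. The annotation release and the settings of cell calling are not given in the sources used here. The gene and barcode files give names only, and the same 28692 genes are listed for both libraries. Groups were taken from the medium named in the labels. The 2 libraries share no animal or batch information in the labels, and the sequencing reads were not used here.

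Cells with fewer than 500 detected genes or more than 25% mitochondrial UMIs were left out, which removed 17 expansion and 30 induction barcodes. Counts were summed over the cells of a library and divided by the library total to give CPM. The log2 ratio of a gene is induction over expansion. Its interval is the exact conditional binomial interval of the 2 counts, levels carry exact Poisson intervals, and shares of cells carry exact Clopper-Pearson intervals, all at 95%. These cover counting error only, since cells of 1 library are not replicates. No statistical test of a difference between the media was made and no p-value was computed; the tests in the closing part compare a value with a bound. A count under 3 UMIs entered a ranking at 3 UMIs, and genes with 1 to 3 UMIs are given by the ratio of their counts with its interval. With 3.43 times more UMIs per cell in the expansion library, low levels are less precise in the induction library, and the files do not tell whether sequencing depth or RNA content made the gap.

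A set of 32 gene lists and the markers of 10 cell types were fixed before the data were examined, as were the rules for naming genes, the alternatives, and 7 lists that lead the comparison. A list member was measured at 10 CPM or more in the higher library, and was called higher or lower at a ratio of at least 2 with an interval excluding a ratio of 1. The median of a list was set against 10000 random lists of the same size, drawn in 20 bins of mean CPM from 7127 genes, as a description of these libraries. Single genes were named by rule: the 12 largest ratios in each direction among genes of at least 100 CPM, without mitochondrial, ribosomal protein and unnamed gene models, and for each list the most abundant member and the 2 largest ratios among members of at least 20 CPM. All members of the list of receptors and mediators of the medium factors could be named, as could 5 genes per cluster by fold over the other cells. Some genes that met these rules are not reported here. Alb, Serpina6, Krt7, Krt19, Cd24a, Oat, Axin2, Lgr5, Tcf7, Tnfrsf19, Znrf3, Rgs5, Egfl7, Hamp, Xist and the genes compared between Xist-positive and Y-positive cells were named after their values had been seen.

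To compare shares of cells across depths, each cell was thinned without replacement to 2000 UMIs with a fixed seed. A cell counted as holding G2/M transcripts with at least 2 of the G2/M genes, and as holding both kinds of transcripts with at least 2 ductal and 5 hepatocyte genes. Clusters were found with scanpy 1.11.5 and igraph 0.11.9 (Leiden, resolution 0.6) on 20 principal components of 2000 variable genes, after scaling to 10000 counts per cell and a log transform, with 15 neighbours. A cluster was called hepatocyte-like when at least 3 of the 10 hepatocyte markers were found in at least 50% of its cells and its UMI share of these markers was at least 0.5 of that of the other cells; the second limit was set after the data had been seen. No cluster had a marker of another cell type among its 10 leading genes. Doublets were not removed in the main values. Scrublet marked 4 expansion and 2 induction cells, and the values without these cells are among the alternatives.

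Coordinates come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, matched by gene ID; 28339 of the 28692 IDs were found. Genes with near-identical copies (the Cyp3a, Cyp2d, Gsta, Saa, Orm and Serpina families, Mt1 and Mt2) and overlapping genes share sequence, so the split of their UMIs is uncertain. The ratio code was tested on simulated Poisson counts drawn from the means of these libraries, which vary by counting error only. There, 99% of 100 genes changed by 1.5 on the log2 scale and 100% of 100 changed by 3 met the size rule among 6785 genes of the induction over expansion comparison, 0% of 6585 unchanged genes did, and 95.4% of intervals held the true ratio. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

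The alternatives were no cell filter, a filter of 1000 genes and 10% mitochondrial UMIs, CPM without mitochondrial and ribosomal protein genes, scaling to the median gene, equal weight for every cell, thinning before summing, no doublets by Scrublet, no cells in the top 5% of UMIs, a minimum of 50 CPM or none, a ratio of at least 1.5, and hepatocyte-like clusters only. For shares they were thinning to 1000 or 4000 UMIs or not at all, another seed, other numbers of genes, resolutions of 0.3 and 1.0, and 1000 variable genes. Chosen after seeing the data were Xist-positive cells only, Y-positive cells only, cells with 8000 to 14000 UMIs only, the ductal list without Clu, the joint clustering as an alternative for the class shares, and 20 further draws of the thinning. Settings that restrict the cells keep the draw of the main values. Xist-positive cells had at least 4 Xist UMIs and at most 1 UMI of the 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d. Y-positive cells had at most 3 Xist UMIs and at least 2 Y-linked UMIs, or 1 with no Xist UMI.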

Results

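Transcripts of single cells were counted in 2 droplet libraries of mouse hepatocytes, the main functional cells of the liver, from C57BL/6 liver. The cells were embedded in a gel of basement membrane proteins and cultured in 3 dimensions. The expansion library came from a medium with 3 uM CHIR99021, an inhibitor of the kinase GSK3 that raises beta-catenin signalling, and 100 ng/mL of the inflammatory cytokine TNF. The induction library came from a medium without these 2 additions and with 3 uM dexamethasone, a synthetic glucocorticoid. Shared by both media were the growth factors HGF (50 ng/mL) and EGF (25 ng/mL), the ROCK inhibitor Y27632 (10 uM) and the TGF-beta receptor inhibitor A83-01 (1 uM). The comparison asked how transcript levels of the cells differed between the medium named for expansion and the medium named for induction. Each group had 1 library, so no difference below has a replicate check or a test, and the 3 factors that differed between the media cannot be separated. Intervals are 95% intervals that cover counting error only.

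The expansion library held 1208 barcodes and 29545561 UMIs (counted transcript molecules), and the induction library held 1275 barcodes and 9305593 UMIs. After cells with fewer than 500 genes or more than 25% mitochondrial UMIs were left out, 1191 and 1245 cells remained. The median cell held 23184 UMIs and 3847 genes in expansion medium and 6765 UMIs and 2001 genes in induction medium, a 3.43-fold gap in UMIs. A count of 3 UMIs, the floor used here, corresponded to 0.102 CPM (counts scaled to the library total) in the expansion library and 0.326 CPM in the induction library. Mitochondrially encoded genes took 6.35% and 6.75% of the UMIs. Genes with at least 50 UMIs in both libraries had a median log2 ratio of 0.22 (induction over expansion), so list medians are given relative to this median gene, and single genes are given as CPM in both libraries.

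Several liver enzymes were among the genes furthest above their expansion level in induction medium. Cyp3a11, a cytochrome P450 that oxidises drugs and steroids, stood at 4.29 CPM in the expansion library (126 UMIs) and at 2013 CPM in the induction library (18526 UMIs), a log2 ratio of 8.88 (8.62 to 9.14). Cps1, the entry enzyme of the urea cycle, stood at 0.238 and 140 CPM, and Bhmt and Gnmt, enzymes of methionine metabolism, at 2.38 and 562 CPM and at 1.16 and 161 CPM. Tat, a tyrosine-degrading enzyme and a classical glucocorticoid target, had 1 UMI in the expansion library and 1393 in the induction library (log2 ratio 12.12, 9.64 to 17.42). Tff3, a secreted trefoil peptide, had 3 and 2843 UMIs (log2 ratio 11.56, 10.01 to 13.84). The other genes among the 12 with the largest ratio were the sulfotransferase Sult1d1, Cyp3a25, the protease inhibitor Timp4, the lipogenic regulator Thrsp, the apolipoprotein Apoa2 and the antithrombin gene Serpinc1, with log2 ratios from 6.11 to 10.24. On GRCm38, Cyp3a11 lies on chromosome 5 from 145854426 to 145879964, and Cyp3a25 on the same chromosome from 145977194 to 146009618. Their sequences are similar, so the split of UMIs between these 2 genes is uncertain. Tat lies on chromosome 8 from 109990437 to 109999803, and Tff3 on chromosome 17 from 31125306 to 31129646.

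Differences in the other direction were smaller. Gsta1, a glutathione transferase, stood at 125 CPM in expansion medium and 14.9 CPM in induction medium (8.40-fold lower, log2 ratio -3.07, -3.33 to -2.82). Pigr, the receptor that carries IgA across epithelia, stood at 150 and 18.8 CPM. The chemokines Cxcl5 (706 and 108 CPM) and Cxcl3 (227 and 39.0 CPM) were 6.51-fold and 5.81-fold lower. The adhesion molecule Vcam1 (166 and 43.5 CPM), the cytochrome P450 Cyp1b1 (383 and 97.9 CPM) and the fatty acid binding protein Fabp5 (365 and 114 CPM) were 3.82-fold, 3.91-fold and 3.21-fold lower. Ang, Gas6, Gsta4 and Rnase4 were also among the 12 genes with the largest ratio in this direction, with log2 ratios from -2.85 to -1.69. Ang (chromosome 14, 51091150 to 51102009) and Rnase4 (51091077 to 51106151) overlap, so their UMIs can be shared. Gsta1 is on chromosome 9 (78230656 to 78242684), and Cxcl5 and Cxcl3 are neighbours on chromosome 5 (90759360 to 90761624 and 90786103 to 90789600).

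**Figure D1:**
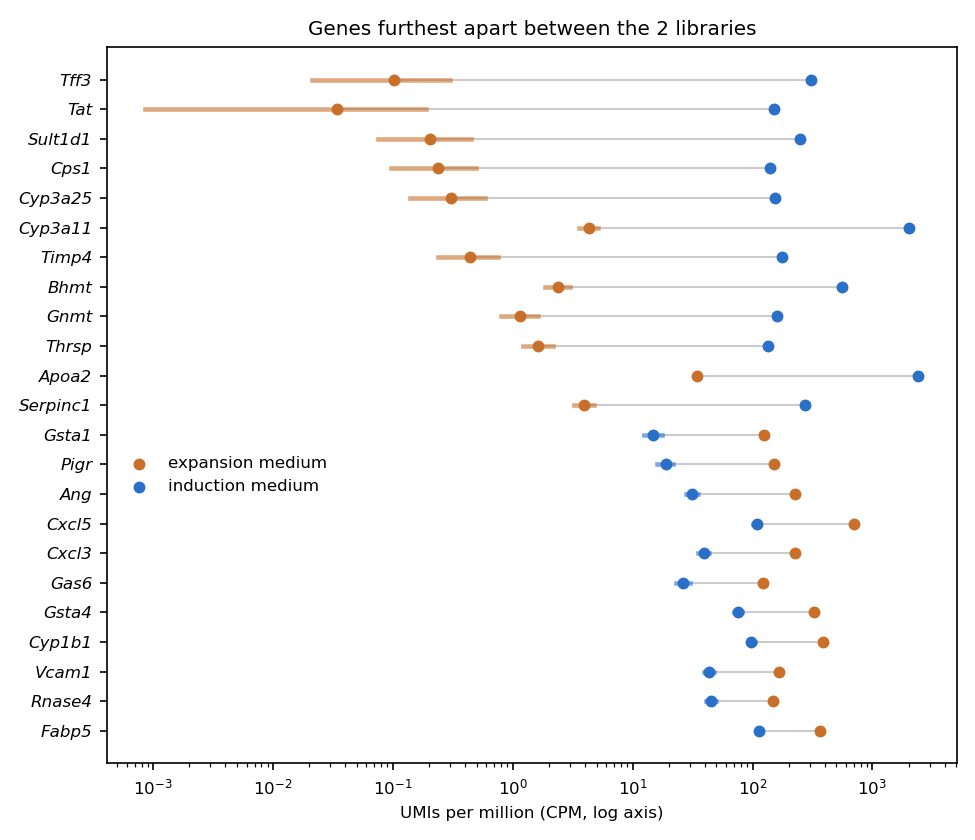
CPM (log axis) of genes furthest apart between the 2 libraries, taken from the 12 largest ratios in each direction. Points are the libraries grown in expansion and induction medium (n = 1 each) and thick lines are exact 95% Poisson intervals for counting error; Cyp3a11 moves from 4.29 to 2013 CPM and Cxcl5 from 706 to 108 CPM.

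Hepatocyte functions stood higher in induction medium across several fixed gene lists. Of the 24 measured genes of secreted hepatocyte proteins, 14 were at least 2-fold higher and 1 was at least 2-fold lower (13 and 1 relative to the median gene). Their median log2 ratio was 1.23, at percentile 100 among 10000 random lists of matched expression. Albumin (Alb) stood at 1737 CPM in expansion medium and 19450 CPM in induction medium, and Apoa2 at 34.5 and 2385 CPM. Transferrin (Trf), the list's most abundant member by the mean of both libraries, stood at 14800 and 9661 CPM, and Serpina6, which encodes the corticosteroid-binding globulin, was the member at least 2-fold lower (63.7 and 12.1 CPM). Of 11 measured hepatocyte transcription factors, 5 were at least 2-fold higher, among them Hnf4a (93.4 and 250 CPM), Prox1 (24.0 and 65.5 CPM) and the retinoid receptor Rxra (20.4 and 100 CPM), and the list median was 0.77 (percentile 99.96).

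Drug, amino acid and sugar metabolism followed the same direction. Of 10 measured genes of xenobiotic metabolism, 8 were at least 2-fold higher (6 relative to the median gene; median 1.55, percentile 100), with Sult1a1 at 5.58 and 117 CPM and Cyp2d22 at 3.98 and 26.6 CPM. Cyp2d22 belongs to a family of near-identical copies, which makes its own count uncertain. Of 8 genes of the urea cycle and amino acid catabolism, 7 were at least 2-fold higher (median 2.04, percentile 100). Arginase (Arg1) had 3 UMIs in the expansion library and 729 in the induction library. All 9 measured genes of hepatic glucose metabolism were at least 2-fold higher (median 4.51, percentile 100). Among them was the glucose transporter gene Slc2a2 (3.57 and 207 CPM).

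Zonal and lipid lists did not share a single direction. Of 6 measured genes typical of periportal hepatocytes, those around the incoming blood, 5 were at least 2-fold higher (median 1.52, percentile 99.94), including Ass1 (3.54 and 23.1 CPM) and Hsd17b13 (276 and 749 CPM). Relative to the median gene, 5 were at least 2-fold higher and 1 lower. Most genes of the periportal list also belong to the urea cycle, glucose or xenobiotic lists above, so its result is not separate from theirs. Of 4 measured pericentral genes, 2 were at least 2-fold lower, Slc1a2 (64.6 and 11.8 CPM) and Lect2 (26.1 and 2.72 CPM), and 1 was at least 2-fold higher, Oat (log2 ratio 1.05), while glutamine synthetase (Glul) stood at 84.0 and 158 CPM. The median of the pericentral list before the shift was taken off, -0.77, turned to 0.37 without a CPM minimum and to 0.76 in cells with Xist, so its direction is not established. Of 9 genes of fatty acid synthesis, 8 were at least 2-fold higher (median 1.38, percentile 100), with Scd1 at 458 and 2481 CPM, Acaca at 32.6 and 218 CPM and Thrsp at 1.63 and 135 CPM. Of 10 genes of fatty acid oxidation, 5 were at least 2-fold higher and 1 lower (median 0.74, percentile 100). Of 16 genes of cholesterol synthesis, 1 was at least 2-fold higher, Sqle (59.3 and 149 CPM), and the list median was -0.20 (percentile 7.72), on the other side of 0 before the shift of the median gene was taken off. Of 3 measured genes of bile acid synthesis and transport, Baat was at least 2-fold higher (11.8 and 54.9 CPM). Relative to the median gene, 1 was at least 2-fold higher and 1 lower, and the list median was 0.67 (percentile 96.9). Whatever their level, 13 of the 15 listed genes had an interval above a ratio of 1 and 1 had an interval below it. The remaining 1 had 0 UMIs in both libraries. None of 8 glycolysis genes differed by 2-fold (median 0.00, percentile 60.2), with Gapdh at 1287 and 1918 CPM.

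Known targets of the glucocorticoid receptor were higher in the medium with dexamethasone. Of 13 measured targets, 12 were at least 2-fold higher (9 relative to the median gene), and the list median was 1.75 (percentile 100). Besides Tat, the transcription factor Zbtb16 stood at 0.783 and 27.8 CPM and the metallothionein Mt1 at 2102 and 4484 CPM. The glucocorticoid receptor gene itself (Nr3c1) stood at 36.8 and 48.3 CPM. Among the receptors and mediators of the medium factors, 1 of 8 measured members was at least 2-fold apart, the TGF-beta receptor Tgfbr1 (29.8 and 69.9 CPM). Relative to the median gene, 1 was at least 2-fold higher and 1 lower, the lower one being Tnf (21.6 and 12.4 CPM). The receptors for EGF and TNF stood at 57.9 and 57.7 CPM (Egfr) and at 48.0 and 59.8 CPM (Tnfrsf1a), and the HGF receptor gene Met had a log2 ratio of 0.43 (0.20 to 0.65). Stress lists lay nearer to the median gene: 1 of 9 immediate early and heat shock genes was at least 2-fold higher (Jun, 108 and 288 CPM; list median 0.28), 3 of 11 genes of the integrated stress and unfolded protein response (Herpud1, 50.7 and 246 CPM; median 0.23) and 0 of 7 NRF2 targets (Gclm, 31.4 and 58.7 CPM; median 0.31). These 3 lists stood at percentiles 95.5, 90.8 and 95.1.

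The lists of NF-kB targets and of chemokines and cytokines had lower medians in the medium without TNF, although most NF-kB targets lay within 2-fold. Of 15 measured NF-kB targets, 2 were at least 2-fold lower in induction medium, Vcam1 and Tnfaip2 (239 and 75.2 CPM), and 13 lay within 2-fold. Whatever their level, 13 of the 17 listed targets had an interval below a ratio of 1, 2 had an interval above it and 2 had an interval that held it. The inhibitor gene Nfkbia, transcribed by NF-kB as its own feedback, stood at 514 and 459 CPM. The list median was -0.53 and stood at percentile 0.01 of the random lists. Before the shift of the median gene was taken off it was -0.31, and it was -0.01 in cells with Xist and -0.46 in cells with Y-linked transcripts. Of 10 chemokine and cytokine genes, 5 were at least 2-fold lower (median -1.13, percentile 0), with Cxcl10 at 61.8 and 6.19 CPM and Cxcl1 at 1073 and 1241 CPM. Transcripts of Tnf were counted in both libraries, at 21.6 CPM in the medium with the cytokine and 12.4 CPM in the medium without. Acute phase proteins, which the liver secretes in inflammation, went both ways: 4 of 14 were at least 2-fold higher and 2 lower. The counts were 3 and 3 relative to the median gene, 4 and 2 in cells with Xist, and 4 and 0 in cells with Y-linked transcripts. Haptoglobin (Hp) stood at 15199 and 15431 CPM, Itih3 at 21.4 and 162 CPM, and Serpina3n at 2 and 303 UMIs (log2 ratio 8.92, 7.05 to 11.97). The median of this list was -0.13, and 0.09 before the shift of the median gene was taken off. Of 4 measured interferon response genes, 2 were at least 2-fold lower, among them Irf7 (33.9 and 16.7 CPM; list median -1.04, percentile 0.43), and of 8 antigen presentation genes 1 was, Psmb8 (log2 ratio -1.04; list median -0.94, percentile 0.01).

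Targets of the Wnt/beta-catenin pathway, on which CHIR99021 acts, were counted at low levels in both media. Of 13 targets, 1 reached 10 CPM in either library, Bambi, at 15.8 and 16.3 CPM. Whatever their level, 3 targets had an interval below a ratio of 1 (Lgr5, Axin2 and Tcf7), 0 had an interval above it, 7 had an interval that held it, among them Tnfrsf19 (log2 ratio 0.35, -0.05 to 0.73) and Znrf3 (-0.06, -0.54 to 0.39), and 3 had 0 UMIs in both libraries. Lgr5 had 58 UMIs (1.97 CPM) in expansion medium and 0 in induction medium, where the limit of a count of 0 is 0.326 CPM. Axin2 had 69 and 9 UMIs, a log2 ratio of -1.26 (-2.45 to -0.26), and Tcf7 had 124 and 20 UMIs (-0.96, -1.72 to -0.27). Beta-catenin (Ctnnb1) and the CHIR99021 target Gsk3b stood at 118 and 160 CPM and at 68.6 and 67.2 CPM. None of 6 measured YAP/TEAD targets differed by 2-fold (Cyr61, 25.6 and 23.4 CPM; list median 0.00, percentile 44.3).

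**Figure D2:**
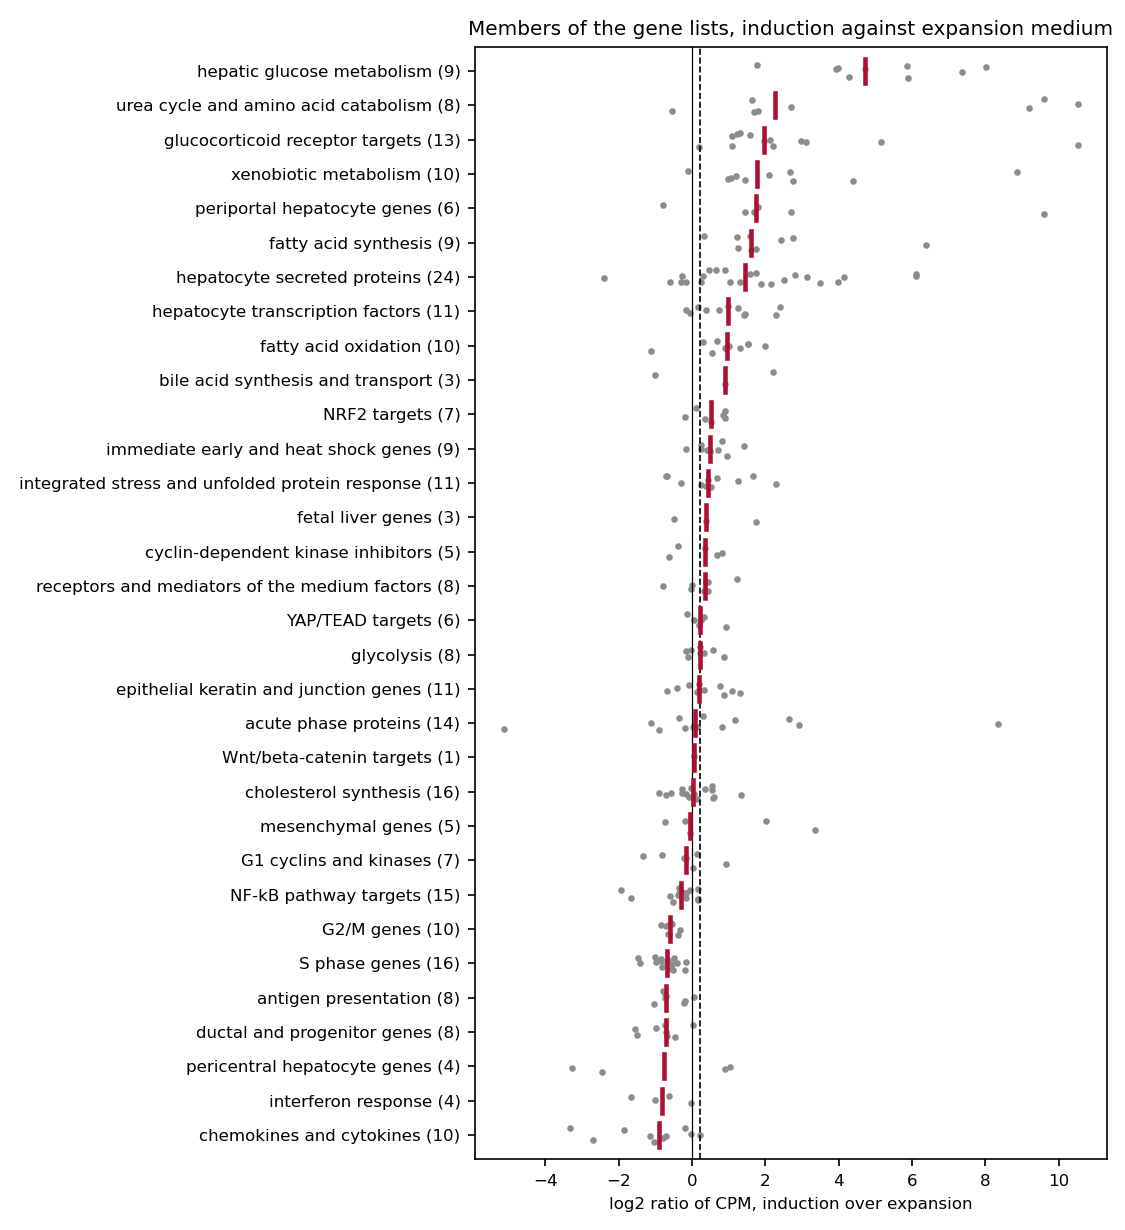
log2 ratio of CPM (induction over expansion, n = 1 library each) of the measured members of the 32 gene lists, with the number of members in parentheses. Grey points are genes (a library with fewer than 3 UMIs enters at 3), red bars are list medians, the solid line is 0 and the dashed line is the median gene at 0.22; glucose metabolism lies furthest right and chemokines and cytokines lie furthest left.

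The list of genes of the bile duct and of liver progenitors had a lower median in induction medium, and Clu and Spp1 carried most of its UMIs. Of 8 measured members, 2 were at least 2-fold lower (3 relative to the median gene, 1 in cells with Xist) and 6 were not, the 2 being the secreted chaperone Clu (7202 and 2471 CPM) and the stem cell marker Prom1 (63.8 and 22.4 CPM). The list median was -0.94 (percentile 0.01). Osteopontin (Spp1) stood at 1307 and 661 CPM. Within hepatocyte-like clusters the gap of Spp1 was wider, at 1302 and 164 CPM (7.93-fold lower), means over clusters that ranged from 422 to 2724 CPM in expansion and from 26.6 to 616 CPM in induction medium. The lowest cluster in each medium held mostly cells with Xist. The duct keratin Krt7 had 0 UMIs in both libraries, and Krt19 had 6 UMIs in expansion and 1 in induction medium, of which 5 and 1 lay in the unnamed clusters. Of 3 measured fetal liver genes, the imprinted RNA H19 was at least 2-fold higher (165 and 557 CPM), and Igf2 stood at 772 and 544 CPM (list median 0.15, percentile 73.8). The ratio of H19 came from cells with Xist (log2 ratio 3.72) more than from cells with Y-linked transcripts (0.34, under 2-fold), and Igf2 had opposite signs in these cells (0.57 and -1.02). Of 5 mesenchymal genes, 2 were at least 2-fold higher, among them S100a6 (14.8 and 151 CPM), while Vim stood at 273 and 165 CPM (list median -0.29, percentile 12.8). Of 11 epithelial keratin and junction genes, 2 were at least 2-fold higher, among them the gap junction gene Gjb2 (57.7 and 143 CPM). Their list median was -0.03, and 0.19 before the shift of the median gene was taken off.

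Hepatocyte and ductal transcripts were found together in single cells, in a smaller share of them in induction medium. After each cell was thinned to 2000 UMIs, 93.5% of expansion cells (1113 of 1191; exact binomial interval 91.9 to 94.8) and 60.8% of induction cells (749 of 1231; 58.1 to 63.6) held at least 2 ductal and progenitor genes and at least 5 genes of secreted hepatocyte proteins. The thinning left out 0 expansion and 14 induction cells with fewer UMIs, and without it the shares were 100% and 91.6%. At least 5 hepatocyte genes alone were found in 99.6% and 99.1% of the thinned cells. Nearly every cell thus met the hepatocyte part of the rule, and the gap between the media came from the ductal part. Clu, which hepatocytes also make, was found in 99.7% and 86.6% of the thinned cells, Spp1 in 72.5% and 15.9%, and Cd24a in 52.9% and 37.0%. With Clu left out of the list, the shares were 68.8% and 30.1%. They were 78.1% and 35.3% at 1000 UMIs and 68.7% and 27.6% with at least 3 ductal genes, so the level of the share, above all in induction medium, depended on the settings. No cluster lacked hepatocyte genes, so free RNA was gauged with Xist instead, an RNA made from the inactive X chromosome of female cells. In cells with at least 2 UMIs of Y-linked genes, Xist stood at 7.23% of the library mean in expansion medium and 0.393% in induction medium. Without the 12 of 599 such expansion cells that had at least 4 Xist UMIs, it was 3.33% in expansion medium. Xist is a nuclear RNA and need not stand for free RNA of other genes, so a difference in free RNA between the libraries stays open for these shares.

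The lists of genes of dividing cells had lower medians in induction medium, but the direction of the G2/M list turned in cells with 8000 to 14000 UMIs. Among 10 measured genes of the G2 and M phases, 0 were at least 2-fold lower (1 relative to the median gene), and the list median was -0.83 (percentile 0.01), with Mki67 at a log2 ratio of -0.71 (-0.98 to -0.45) and Ube2c at 46.4 and 32.1 CPM. In the 109 expansion and 349 induction cells with 8000 to 14000 UMIs, the G2/M median was 0.47, against -0.61 in all cells, both before the shift of the median gene was taken off, and it was -0.21 in cells with Xist and -0.90 in cells with Y-linked transcripts. That range lies below the lower quartile of expansion cells (17720 UMIs) and reaches above the upper quartile of induction cells (8885 UMIs). The clusters led by genes of dividing cells (239 expansion and 90 induction cells) had medians of 25260 and 9845.5 UMIs, against 23184 and 6765 in all cells. The range thus takes different parts of the 2 libraries and does not separate depth from the choice of cells. Of 16 S phase genes, 3 were at least 2-fold lower (7 relative to the median gene; median -0.89, percentile 0), with Dut at 37.3 and 25.8 CPM. At 2000 UMIs per cell, 12.6% of expansion cells (150 of 1191; 10.8 to 14.6) and 6.82% of induction cells (84 of 1231; 5.48 to 8.38) held at least 2 G2/M genes. The shares were 46.0% and 9.64% without thinning. With at least 3 genes they were 6.47% and 5.04%, and the interval of that difference, -3.36 to 0.483 percentage points, held 0. Of 7 G1 cyclins and kinases, 1 was at least 2-fold lower (list median -0.39, percentile 3.75). Ccnd1 stood at 553 and 558 CPM and Cdk4 at 158 and 90.3 CPM. None of 5 inhibitors of cyclin-dependent kinases differed by 2-fold (list median 0.14, percentile 75.3), with Cdkn1a at 102 and 179 CPM and Cdkn2a at 72.3 and 55.7 CPM.

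Cells with G2/M transcripts held on average a smaller share of hepatocyte transcripts than the other cells of their library, by less than the spread between cells. In expansion medium, the genes of secreted hepatocyte proteins took 4.03% of the thinned UMIs (3.96 to 4.10) in cells with at least 2 G2/M genes and 4.62% (4.59 to 4.65) in the other cells, with an SD over cells of 1.97 and 2.42. Over 20 further draws of the thinning, the expansion difference ranged from -0.689 to -0.300 percentage points, wider than its counting interval. It came close to 0 in some draws when the kinds of cells were separated, ranging from -0.708 to -0.0274 points within cells with Xist and from -0.703 to -0.0675 within cells with Y-linked transcripts. In induction medium the shares were 5.09% (4.99 to 5.20) and 7.70% (7.66 to 7.73), with an SD over cells of 2.82 and 3.80, and the difference ranged from -2.86 to -2.45 points over the draws. The range was -2.88 to -2.37 points within cells with Xist and -2.44 to -1.76 within cells with Y-linked transcripts.

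**Figure D3:**
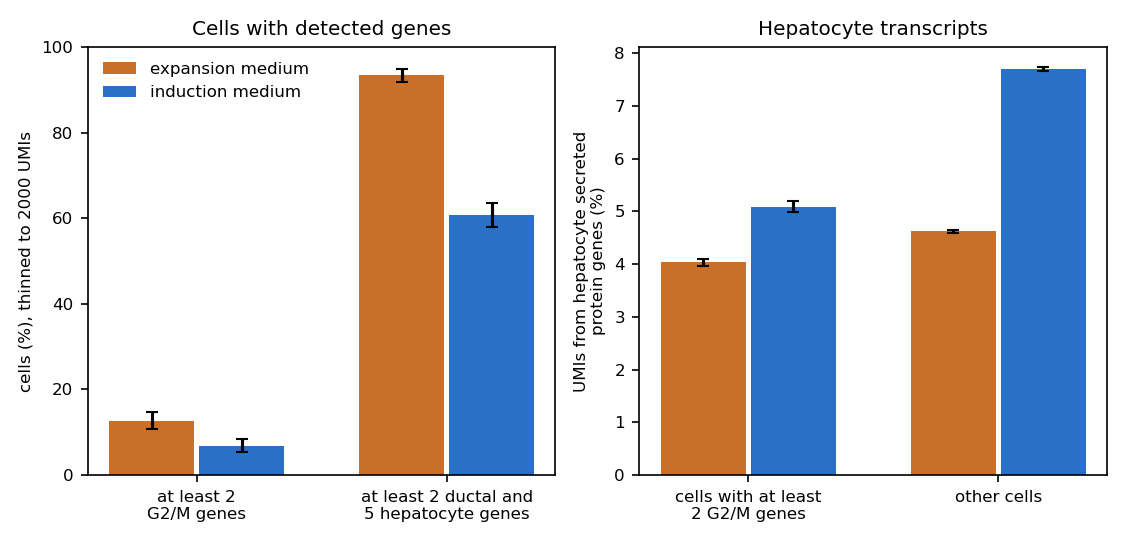
Left, percent of cells with at least 2 G2/M genes, or with at least 2 ductal and 5 hepatocyte genes, after thinning to 2000 UMIs; right, percent of thinned UMIs from genes of secreted hepatocyte proteins in cells with at least 2 G2/M genes and in the other cells. Bars are 1 library each and error bars are exact 95% binomial intervals for counting error; the share with both kinds of genes is 93.5% in expansion and 60.8% in induction medium.

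Of 107 genes called higher or lower in any list, 0 had the other sign in cells with Xist or in cells with Y-linked transcripts, and 21 were under 2-fold apart in 1 of these kinds of cells, among them H19, Serpina6, Prom1, Mt1 and Irf7. Both kinds are subsets of the cells in which the genes were called, so agreement in sign is favoured by the choice of genes.

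Ribosomal protein genes took 32.8% of the UMIs in expansion medium and 22.3% in induction medium. Of 81 such genes, 9 were at least 2-fold lower and 0 higher, with a median of -0.71 relative to the median gene. In the 109 expansion and 349 induction cells with 8000 to 14000 UMIs, where depth is closer, the shares were 30.9% and 22.8%. As for the G2/M list, this range takes low-UMI expansion cells and high-UMI induction cells. It does not separate depth from the choice of cells.

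Among markers of other liver cell types, those of cholangiocytes, the cells of the bile ducts, were the most abundant. Of 8 cholangiocyte markers, 4 reached 10 CPM, and the sum of all 8 was 1841 and 1002 CPM, most of it from Spp1 and Cd24a (415 and 256 CPM). Of the markers of macrophages, T or NK cells, B cells, neutrophils, mesothelial cells and erythroid cells, none reached 10 CPM. Among fibroblast and endothelial markers, Rgs5 reached 402 and 179 CPM and Egfl7 38.8 and 33.6 CPM, while the other 9 and 7 stood at or below 1 CPM. When each library was clustered alone, 7 clusters were found in each. Clusters holding 97.1% of expansion cells (1157 of 1191; 96.0 to 98.0) and 92.6% of induction cells (1153 of 1245; 91.0 to 94.0) were hepatocyte-like. The remaining cluster of each library stayed unnamed, with 34 cells (2.85%) and 92 cells (7.39%). At resolution 0.3, and without the cells marked by Scrublet, the 34 expansion cells fell into larger hepatocyte-like clusters of 428 and 135 cells, although Scrublet had marked 0 of the 34. The UMI share of the unnamed cluster from hepatocyte markers was 0.199 and 0.369 of that of the other cells, under a limit of 0.5 that was set after the data had been seen. The order of the 2 shares of hepatocyte-like cells depended on the clustering: at resolution 1.0 they were 91.2% and 92.6%, and with both libraries clustered together 78.1% and 95.2%. Of the 261 expansion cells that were not hepatocyte-like in the joint clustering, 219 were in a cluster whose share from hepatocyte markers, 0.491, lay just under the limit. There the share is set against cells of both libraries, and the hepatocyte markers summed to 31555 CPM in expansion and 55940 CPM in induction medium. That lowers the relative share of expansion clusters. In the joint clustering, 7 of 9 clusters took over 90% of their cells from 1 library, so such a cluster can reflect the library as much as a kind of cell, and 1 cluster took similar numbers from both, 42 expansion and 58 induction cells.

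**Figure D4:**
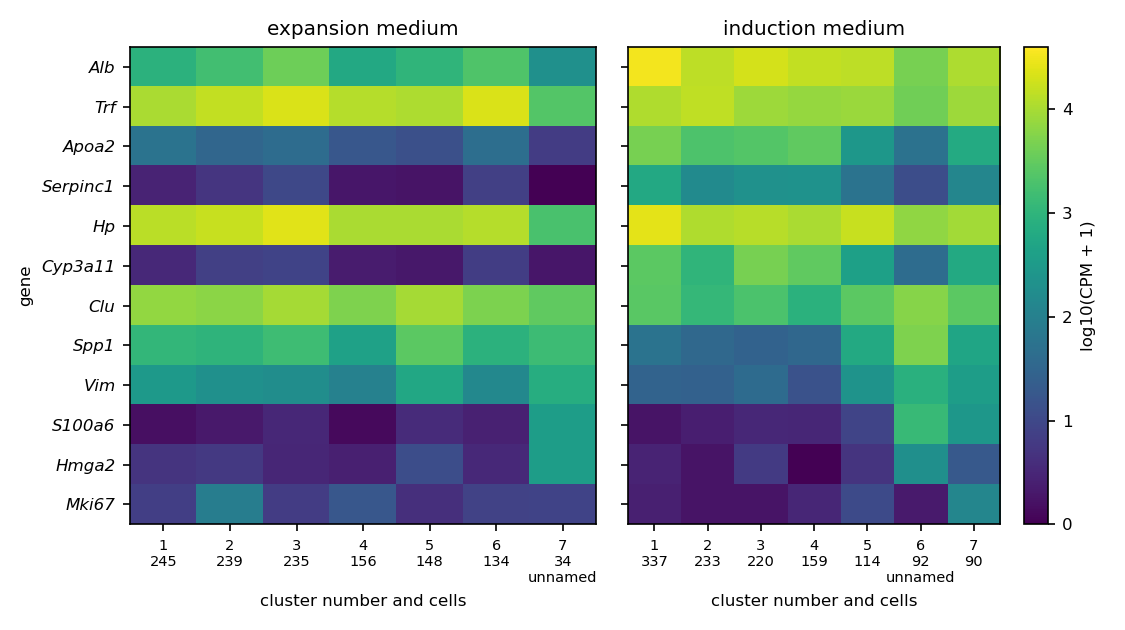
log10(CPM + 1) of 12 genes in the 7 clusters of each library, which were clustered alone, so that cluster numbers do not match between the panels. The numbers under the columns are the cluster and its cells; Spp1 stands at 1436 CPM in the unnamed expansion cluster and 1302 CPM in the other expansion cells, and at 5226 and 164 CPM in induction medium.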

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

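All tests in this part were chosen after the result was seen, except the test of immediate early genes.

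Cells with Xist were present in both libraries, a signal in a transcript that the comparison of media does not use. At least 4 Xist UMIs were found in 30.2% of expansion cells (360 of 1191; exact binomial interval 27.6 to 32.9) and 30.8% of induction cells (384 of 1245; 28.3 to 33.5), where a count of 0 would allow 0.252% and 0.241%. Free RNA would put Xist in cells with and without Y-linked transcripts alike, but the share with Xist among cells with at least 2 Y-linked UMIs was 0.0273 of that among cells with none in expansion medium and 0 in induction medium, which argues against it. A mixture of cells from animals of both sexes needs the 2 signals to exclude each other: of the cells with either, 1.27% in expansion and 0% in induction medium had both. A candidate explanation is therefore that each library pools hepatocytes of at least 1 female and 1 male animal; the labels do not give sex, and no other biological explanation was tested.

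Of 15 measured NF-kB targets, 13 lay within 2-fold of each other in a medium with and a medium without TNF. Handling may have raised these targets through the immediate early response. For this, induction cells without immediate early UMIs were to hold under 0.5 of the NF-kB UMIs of cells with at least 2. The ratio was 0.880 (0.797 to 0.969; 154 and 849 cells), so the bound was not met, although cells without these UMIs held slightly fewer. The test cannot decide, because handling would reach all cells of a library and a cell can lack these UMIs by counting alone. Handling therefore stays open. Too few UMIs are argued against by the interval of the summed list, whose width was 0.0501 on the log2 scale around a log2 ratio of -0.33. Tnf made by the cells themselves may act in the induction medium, where 114 Tnf UMIs were counted; no value here measures the protein, so this stays open. The medium, which also differed in dexamethasone and CHIR99021, and the time since the last TNF stay open as well, untested.

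An unnamed cluster of each library (34 and 92 cells) held few hepatocyte transcripts, with Alb at 11.5% and 23.3% of the library mean. Cells of another listed liver type are argued against: at most 1 marker of any such type, Spp1 in induction medium, reached 100 CPM and 4 times the level of the other cells. Cells of a single donor animal are argued against as well, since the rarer sex made up 41.9% and 36.5% of the cells with a sex call. Free RNA as the source of the remaining Alb cannot be told apart from expression, because Alb relative to the library was 1.59 times the relative Xist level of cells with at least 2 Y-linked UMIs in expansion medium (lower limit 1.27), under the 3 set as the bound, while it was 59.3 times in induction medium. The expansion value leans on 12 of 599 such cells that had at least 4 Xist UMIs. Without them relative Xist was 3.33% and not 7.23%, against 11.5% for Alb. Xist is also a nuclear RNA and need not stand for free Alb RNA. No other biological explanation was tested, a cell type outside the marker lists stays open, and the 34 expansion cells, of which Scrublet marked 0, joined larger hepatocyte-like clusters at resolution 0.3 and without Scrublet doublets (428 and 135 cells).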

How the results depend on the processing

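The settings with Xist-positive, Y-positive or 8000 to 14000 UMI cells, the ductal list without Clu, the joint clustering, another seed for the hepatocyte transcripts and the 20 further draws were chosen after the data were seen; all other settings were fixed before. Of 288 values of the 24 named genes across 12 settings, 0 changed sign, 178 lay within the counting interval of the main value and 110 moved beyond it; the widest ranges were 4.14 to 10.24 for Bhmt and 4.49 to 9.57 for Cps1, and Ang went from -4.35 to -1.71. Of 103 counts for the 7 leading lists, 91 lay within 1.5 times the main count. The members of xenobiotic metabolism higher in induction medium were 13 of 16 without a CPM minimum, which adds genes tested. Ductal members lower in induction medium were 6 at a ratio of 1.5, 4 in hepatocyte-like clusters and 1 in Xist-positive cells. G2/M members lower were 3 with CPM free of mitochondrial and ribosomal protein genes, 1 relative to the median gene, 1 with equal cell weights, 3 after thinning to 2000 UMIs, 1 without the top 5% of cells by UMIs, 6 at a ratio of 1.5 and 1 in Y-positive cells, against 0 in the main values, and Wnt targets lower were 2 without a CPM minimum. Of 444 list medians, 30 in 12 lists had the opposite sign to the main value. In 3 of them the main median stood apart from random lists (in the lowest or the highest 2.5% of them): pericentral genes were at 0.37 without a CPM minimum and at 0.76 in Xist-positive cells, and G2/M genes at 0.47 in the 109 expansion and 349 induction cells with 8000 to 14000 UMIs. The cause was not tested, but this range takes low-UMI expansion cells and high-UMI induction cells. The difference in cells with G2/M genes (induction minus expansion, -5.77 percentage points) was -2.46 at 1000 UMIs, -10.5 at 4000, -36.4 without thinning, -14.9 with at least 1 gene and -1.43 with at least 3, and it was -5.65 in Xist-positive and -5.49 in Y-positive cells. Over 20 further draws it ranged from -7.44 to -5.09 in all cells and from -9.07 to -3.01 in Xist-positive cells, where the interval held 0 in 4 draws. The difference in cells with ductal and hepatocyte genes (-32.6) was -42.7 at 1000 UMIs, -16.1 at 4000, -8.43 without thinning, -41.1 with at least 3 ductal genes and -38.6 without Clu. Over 20 draws it ranged from -26.5 to -17.9 in Xist-positive and from -41.7 to -35.0 in Y-positive cells. Both the UMIs kept and the number of genes required moved the size of these differences; the cause was not tested. The difference in hepatocyte-like cells (-4.53) was -7.39 at resolution 0.3, -8.13 without Scrublet doublets, 1.43 at resolution 1.0, 2.65 without the cell filter and 17.1 with both libraries clustered together, where 219 expansion cells lay just under the limit (0.491), so its direction is not established. In the joint clustering, expansion clusters were set against induction cells as well, which hold more hepatocyte transcripts and so lower the relative share. The cause of the other moves was not tested. Hepatocyte transcripts in cells with G2/M genes minus the other cells (-0.588 and -2.61 percentage points of UMIs in expansion and induction medium) were -0.703 and -2.88 with at least 3 genes, -0.659 and -2.97 in hepatocyte-like clusters, -0.300 in expansion medium with another seed, and -2.39 in induction medium at 1000 UMIs. In expansion medium the draw alone moved the value (-0.689 to -0.300 over 20 draws); the cause of the other moves was not tested. Depth limits the lowest genes most: 3 UMIs are 0.326 CPM in the induction library and 0.102 CPM in the expansion library.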

Other observations

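The comparisons in this part were chosen after the data were seen.

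Osteopontin (Spp1) differed between clusters in both media. The unnamed expansion cluster held 1436 CPM of Spp1 and the other expansion cells 1302 CPM, whereas the unnamed induction cluster held 5226 CPM and the other induction cells 164 CPM. Among the other clusters, Spp1 ranged from 422 to 2724 CPM in expansion medium and from 26.6 to 616 CPM in induction medium. Clusters also differed in sex call, and the lowest in each medium held mostly Xist-positive cells (148 against 2 Y-positive cells in expansion medium, 205 against 1 in induction medium). Induction clusters of mostly Y-positive cells also held little Spp1, from 33.4 to 54.5 CPM. The unnamed clusters also held more S100a6 (366 against 1.41 CPM in expansion medium, 1237 against 32.4 CPM in induction medium, where a cluster of 90 cells with G2/M genes held 274 CPM and the others 0.756 to 7.68 CPM), more of the fetal chromatin protein gene Hmga2 (363 against 4.38 CPM, 194 against 4.10 CPM) and more of the cell cycle inhibitor gene Cdkn2a (286 against 64.1 CPM, 298 against 29.4 CPM) than the other cells, among which a hepatocyte-like expansion cluster of 148 cells held 167 CPM of Cdkn2a. In the joint clustering, 34 of the 34 and 54 of the 92 cells of these clusters fell into clusters that stayed unnamed, which together held 261 expansion and 60 induction cells. Hamp, the iron hormone hepcidin, fell outside the rule for named genes and had 449 UMIs in expansion medium and 4 in induction medium (log2 ratio -5.14, -7.02 to -3.77).

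Xist-positive and Y-positive cells were compared within each library, with 348 and 685 cells in expansion medium and 384 and 509 in induction medium. Of 1828 genes, 10 were at least 2-fold apart in the same direction in both libraries. Serpina7, which encodes the thyroxine-binding globulin, stood at 109 CPM in Xist-positive and 22.1 CPM in Y-positive expansion cells and at 78.6 and 11.7 CPM in induction cells, and Noct had log2 ratios of Xist-positive over Y-positive cells of 2.46 and 3.10. In the other direction, Orm1 stood at 115 and 466 CPM and at 130 and 525 CPM, and Hsd17b13 at 102 and 358 CPM and at 318 and 924 CPM. The X-linked gene Eif2s3x stood at 103 and 59.8 CPM and at 106 and 60.4 CPM. Sex and animal cannot be separated here. All 24 named genes had the same sign of induction over expansion in Xist-positive and in Y-positive cells, with Gsta1 at -1.25 and -3.96 and Rnase4 at -0.64 and -2.90 on the log2 scale. The genes were picked for large ratios in all cells, which include these, so agreement in sign is favoured by the choice. The difference between the 2 kinds of cells was not tested.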
